A study of Ovis aries with 24 samples.

How the data were processed

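Poly(A) selection, read length and read layout are not given in the sources used here. Per the labels, pituitaries of ovariectomized Western white faced ewes were dispersed and cultured, and 24 hours later the cells were infected with an adenovirus that expresses green fluorescent protein (GFP) in gonadotropes. After 3 days the cells received ethanol (vehicle) or 10 nM estradiol (E2) for 6 hours, and cells were collected by fluorescence-activated sorting. Libraries were made from 500 ng of total RNA with a TruSeq kit and sequenced on an Illumina HiSeq. There were 24 libraries in 4 groups of 6: sorted vehicle, sorted E2, unsorted vehicle and unsorted E2.

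The deposited counts are whole numbers of reads per gene, 1 column per library, in 3 tables of 27054 features with Ensembl sheep gene identifiers. The submitters' processing notes name featureCounts 1.5.1 as the counter. The aligner, genome build and strand setting are not given in the sources used here, so overlapping genes on opposite strands are not told apart and no coordinates are given. The deposited log2 fold changes, log2 mean CPM and p-values of 3 comparison tables are, per the file headers, from the authors' edgeR runs; the edgeR version, filter and test are not given in the sources used here. These 3 authors' tables were compared with the fits below and were otherwise not used. The 12 vehicle libraries stand in 2 count tables each, and 0 values differed between the copies. Of the features, 9994 have no gene name, 2644 carry only the name of an RNA family and 21 names are bare numbers; 14395 have a symbol that could be matched to the gene lists. Sheep growth hormone genes come in near-identical copies, so reads counted for GH may be incomplete or shared.

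Total counts were 4.19 to 6.19 M in the 12 libraries with replicate numbers 1 to 3 and 19.2 to 37 M in the 12 with numbers 4 to 6, so each group holds 3 libraries of each depth. These 2 depth sets are treated as possible batches, although the labels name none, and fold changes given for a set come from fits of that set with the replicate block. Reads are not independent molecules, and counting error is only part of the spread between libraries.

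Each comparison was fitted with edgeR 4.0.16 in R 4.3.3: TMM normalization, the filterByExpr filter on the groups compared, glmQLFit with robust estimation and the 2-sided quasi-likelihood F-test. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested are called changed. The 4 comparisons were sorted against unsorted vehicle libraries, E2 against vehicle in sorted cells, E2 against vehicle in unsorted cells, and the difference of the E2 effects (the interaction, over all 24 libraries). Fold changes are log2 values with a standard error taken as the fold change over the square root of its F statistic. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over 6 libraries. Principal components were taken on log2 CPM with a prior count of 2. Calls of the E2 comparisons were compared by Fisher's exact test among genes tested in both.

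Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison with at least 3 tested members. The 26 lists were gonadotrope, somatotrope, lactotrope, corticotrope, thyrotrope, folliculostellate and stem cell, endothelial, fibroblast and pericyte, and immune cell markers, red blood cell genes, estrogen target genes from other tissues, GnRH signalling, the activin, inhibin and BMP pathway, steroid receptors and coregulators, secretory granule and exocytosis genes, immediate-early, interferon-stimulated, inflammatory, heat shock, endoplasmic reticulum stress, p53 target and cell cycle genes, cholesterol synthesis, voltage-gated ion channels, ribosomal proteins and mitochondrially encoded genes. Some genes stand in several lists, such as TRHR in the lactotrope and thyrotrope lists. EGR1, JUN, FOS, ATF3 and DUSP1 stand in the immediate-early and GnRH signalling lists. Levels of 12 fixed genes were also compared by 2-sided exact permutation tests of log2 CPM, 6 against 6.

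The genes named follow a rule: in each 2-group comparison the 10 largest rises and 10 largest falls among called genes with a symbol and a mean of at least 5 CPM in the higher group, in the interaction the 5 largest each way, 14 fixed pituitary and estrogen genes, and up to 4 members of each list with the smallest p. From this rule the text gives a selection, and results for 2 genes are not reported here. The fixed genes PGR and NR0B1 have no feature of that name and are not analysed here, and GH1 is measured under the name GH. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined.

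No label says that equal replicate numbers share a culture. It was checked in the counts: in libraries centred by group, those with the same number correlated at r = 0.290 to 0.513 between sorted and unsorted vehicle libraries (highest for different numbers 0.183). For E2 and vehicle the values were 0.661 to 0.859 in sorted cells (0.512) and 0.570 to 0.837 in unsorted cells (0.489), and each library correlated best with its own number in 6 of 6 cases. A fit with replicate number as a block was therefore run beside each comparison, and its values stand beside the unblocked ones where they change the call of a gene or list discussed. Counts of list members are from the unblocked fit where no block is named. Whether numbers stand for separate animals is not given in the sources used here, so the p-values measure the spread between these cultures.

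Alternatives were another normalization (DESeq2's size factors), other filters, the edgeR exact test, limma-voom, DESeq2 1.42.0, stricter thresholds, a shared fit of all libraries, the replicate block and each library left out in turn. After seeing the data, a depth set term, fits within each set, thinning of every library to the lowest total, and fits without number 1 were added. The fits were tested on simulated data in which 200 genes of the observed spread were changed. Without the block, genes changed 2-fold were recovered at 54.5% in the sorted against unsorted design, 65.7% and 63.1% in the E2 designs for sorted and unsorted cells, and 37.9% in the interaction. With the block these shares were 86.4%, 100%, 98.5% and 90.9%, and 5.56% to 10.0% of the calls were false. These false shares were above the share that the adjusted p threshold allows, so some genes called only with the block may be false. Simulated data cannot show whether same-numbered libraries share a culture, so the higher recovery is no evidence for the pairing.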

Results

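The data are 24 RNA-seq libraries of cultured pituitary cells from ovariectomized ewes, in which an adenovirus had marked gonadotropes, the cells that secrete the gonadotropins, with GFP. Sorted cells (labelled gonadotropes) and unsorted cells had received vehicle or 10 nM E2 for 6 hours, with 6 libraries in each of the 4 groups. Total counts ranged from 5.75 to 22.5 M in sorted vehicle, 5.03 to 37 M in unsorted vehicle, 4.19 to 21.9 M in sorted E2 and 5.58 to 37 M in unsorted E2 libraries. The first principal component (50.1% of the variance) separated sorted from unsorted libraries, and the second (17.6%) separated replicates 1 to 3 from the deeper replicates 4 to 6.

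The first comparison addresses what the sort enriched, in vehicle-treated cells. Gonadotrope genes were higher in sorted libraries. CGA (ENSOARG00000013153), the alpha subunit shared by the glycoprotein hormones, stood at 2787 ± 758 CPM (SD, n = 6) in sorted and 423 ± 177 CPM in unsorted libraries. It rose by 2.74 ± 0.28 (log2 ± SE; adjusted p = 3.8e-06, edgeR), with 2.81 in replicates 1 to 3 and 2.80 in replicates 4 to 6. GNRHR (ENSOARG00000007526), the receptor for gonadotropin-releasing hormone, stood at 5.61 ± 2.24 against 0.728 ± 0.255 CPM and rose by 2.98 ± 0.32 (adjusted p = 4.4e-06; 2.95 and 2.93 in the 2 sets). NR5A1 (ENSOARG00000013422), a transcription factor of gonadotropes, stood at 31.2 ± 10.8 against 5.56 ± 3.27 CPM and rose by 2.45 ± 0.37 (adjusted p = 0.00010).

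The hormone-specific gonadotropin subunits followed. LHB (ENSOARG00000012583), of luteinizing hormone, stood at 1029 ± 527 CPM in sorted and 251 ± 213 CPM in unsorted libraries, a rise of 2.06 ± 0.53 (adjusted p = 0.0070). FSHB (ENSOARG00000015425), of follicle-stimulating hormone, stood at 147 ± 65.7 against 40.5 ± 26.0 CPM, a rise of 1.86 ± 0.40 (adjusted p = 0.0019). Of 8 gonadotrope markers tested 6 rose, as many when adjusted over the list alone, and 2 did not pass. Their median was 1.96 (camera adjusted p = 0.0075; adjusted p = 0.189 with an estimated correlation).

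**Figure D1:**
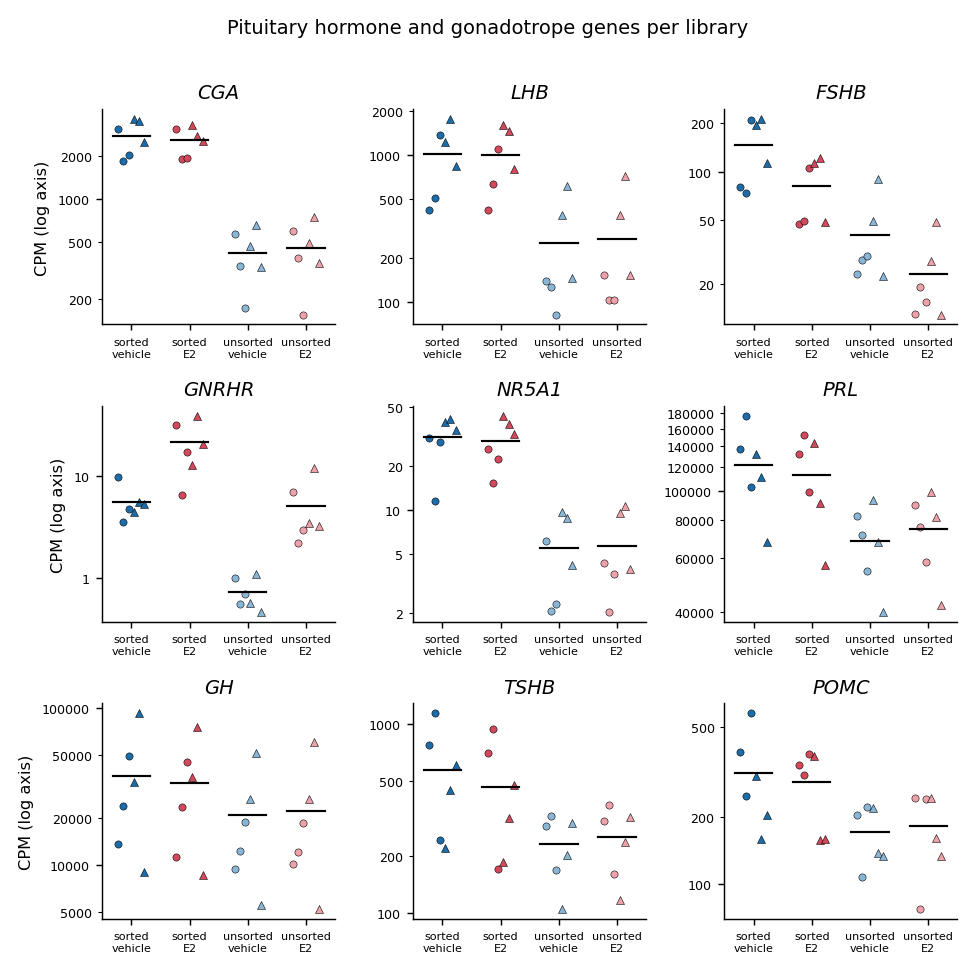
CPM (log axis) of 9 pituitary genes in each library of the 4 groups, with circles for replicates 1 to 3, triangles for replicates 4 to 6 and bars for group means. CGA averaged 2787 CPM in sorted and 423 CPM in unsorted vehicle libraries.

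Hormone genes of other pituitary cells were also higher in sorted libraries, by smaller amounts. PRL, the prolactin gene of lactotropes, was the most counted gene in all 24 libraries, with 12 ± 3.36% of counts in sorted and 6.78 ± 1.84% in unsorted vehicle libraries, and it rose by 0.85 ± 0.24 (adjusted p = 0.0093). TSHB, the thyrotropin subunit gene, rose by 1.33 ± 0.42 (adjusted p = 0.018), from 232 ± 87.2 to 574 ± 352 CPM. POMC, the corticotropin precursor gene, rose by 0.90 ± 0.30 (adjusted p = 0.025), a call lost without sorted vehicle replicate 3 or unsorted vehicle replicate 2, 5 or 6 (adjusted p up to 0.057). GH, the growth hormone gene, was 0.86 higher but did not pass the unblocked test (adjusted p = 0.26), and with the replicate block it was 0.81 ± 0.13 higher (adjusted p = 0.00023). Near-identical copies of this gene in sheep leave its counts uncertain. Of 6 lactotrope markers 5 rose (median 0.74; camera adjusted p = 0.037; adjusted p = 0.189 with an estimated correlation). The receptor gene TRHR, a member of the lactotrope and thyrotrope lists, rose by 0.87. Of 5 somatotrope markers 3 rose, among them the transcription factor POU1F1 by 0.86, and of 4 corticotrope markers 2 rose, among them the prohormone convertase PCSK1 by 2.81. These lists passed with the block (adjusted p = 0.031 and 0.022; adjusted p = 0.333 for both with an estimated correlation) but not without (adjusted p = 0.069 for both). Of 4 thyrotrope markers 2 rose and 1 fell (adjusted p = 0.35), or 3 and 1 adjusted over the list alone.

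Exact 2-sided permutation tests of log2 CPM gave adjusted p values of 0.00866 to 0.0354 for 11 of the 12 fixed genes and 0.273 for GH. All 12 were higher in the sorted library in 6 of 6 same-numbered comparisons, for which an exact sign-flip test gives 0.0313, the smallest p it can give. ESR1, the estrogen receptor gene, stood at 50.3 ± 7.73 CPM in sorted and 31 ± 7.31 CPM in unsorted libraries, a rise of 0.71 ± 0.15 (adjusted p = 0.0011). S100B, a folliculostellate marker, rose by 0.69 ± 0.20 (adjusted p = 0.0091). GREB1, an estrogen-regulated gene, rose by 1.71 ± 0.65 (adjusted p = 0.043), a call lost in 8 of the 12 fits that each left out 1 library (adjusted p up to 0.11) and kept without sorted vehicle replicate 3, 5 or 6 or unsorted vehicle replicate 1.

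Genes of the regulated secretory pathway and of excitable cells rose. Of 24 secretory granule and exocytosis genes 20 rose and none fell by the edgeR test (median 0.89; camera adjusted p = 2.9e-08; adjusted p = 0.0219 with an estimated correlation and 0.277 with block and estimated correlation). Among them the granin gene SCG2 rose by 1.49 ± 0.14, carboxypeptidase E (CPE) by 1.00 ± 0.09 and the synaptotagmin SYT4 by 1.26 ± 0.12. Of 30 voltage-gated ion channel genes 18 rose and 2 fell (median 0.69; camera adjusted p = 0.00038; adjusted p = 0.126 with an estimated correlation). The calcium channel gene CACNA1D rose by 1.30 and the sodium channel gene SCN8A by 0.98. Of 12 steroid receptor and coregulator genes 6 rose, 7 when adjusted over the list alone, and 1 fell (median 0.47; camera adjusted p = 0.016; adjusted p = 0.126 with an estimated correlation). Of 31 GnRH signalling genes 15 rose and 7 fell (camera adjusted p = 0.065).

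Markers of non-endocrine cells were lower in sorted libraries. Of 11 fibroblast and pericyte markers 7 fell and 1 rose (median -2.38; camera adjusted p = 0.0058; adjusted p = 0.189 with an estimated correlation). Smooth muscle actin ACTA2 fell by 2.90 ± 0.20 and the collagen gene COL1A2 by 2.82 ± 0.26. Of 9 folliculostellate and stem cell markers 7 fell and 2 rose (median -1.87; camera adjusted p = 0.0060; adjusted p = 0.126 with an estimated correlation). The transcription factor genes SOX2 and SOX9 fell by 2.95 ± 0.29 and 2.62 ± 0.27. Of 10 endothelial markers 7 fell, among them PECAM1 by 2.07 ± 0.34, and the list passed only with the block (camera adjusted p = 0.053 without, 0.041 with; adjusted p = 0.366 with block and estimated correlation). Of 6 immune cell markers 3 fell, among them the macrophage receptor gene CSF1R by 4.61 ± 0.57, and the T cell gene CD3E rose by 1.21 (list adjusted p = 0.13). Of the 8 red blood cell genes, 3 have a named feature and 0 reached the counts needed for testing.

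Genes of dividing cells and of inflammation were lower as well. Of 21 cell cycle genes 20 fell (median -1.65; camera adjusted p = 2.9e-08; adjusted p = 0.189 with an estimated correlation). The replication licensing gene CDC6 fell by 2.23 ± 0.16 and the mitotic kinase gene AURKA by 2.14 ± 0.22. Of 10 inflammatory genes 7 fell, 8 when adjusted over the list alone, and 1 rose (median -2.0; camera adjusted p = 0.0082; adjusted p = 0.339 with an estimated correlation). The cytokine gene IL1B stood at 0.109 ± 0.172 CPM in sorted and 6.22 ± 7.05 CPM in unsorted libraries and fell by 5.52 ± 0.93 (adjusted p = 0.00026), but had too few counts for testing in replicates 1 to 3. The chemokine gene CCL2 fell by 3.95 ± 0.84 and the cytokine gene LIF by 2.96 ± 0.39. Of 27 activin, inhibin and BMP pathway genes 12 fell and 4 rose, or 13 and 5 adjusted over the list alone, and the list did not pass (adjusted p = 0.069). INHBA, the activin subunit gene, fell by 2.49 ± 0.17, and FSTL3, which encodes an activin-binding protein, by 2.72 ± 0.23.

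**Figure D2:**
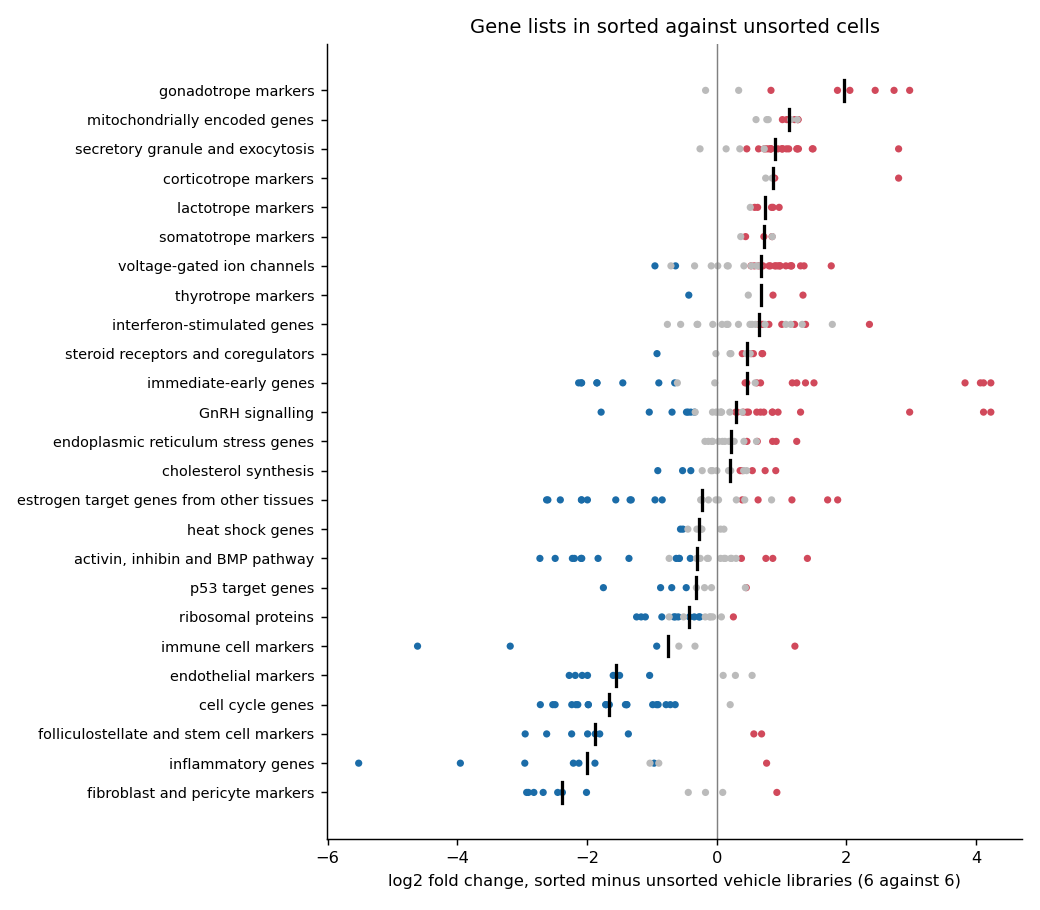
Log2 fold change, sorted minus unsorted vehicle libraries, of each tested member of the gene lists, coloured red where it rose, blue where it fell and grey where it did not pass, with a bar at each list's median. The medians of the secretory granule list (0.89) and the fibroblast and pericyte list (-2.38) lie on opposite sides of 0.

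The 3 largest rises among genes with a symbol were in immediate-early genes, which cells transcribe within minutes of a stimulus. EGR1 stood at 233 ± 75.1 CPM in sorted and 12.1 ± 4.35 CPM in unsorted libraries and rose by 4.23 ± 0.27 (adjusted p = 5.8e-08). FOS stood at 395 ± 110.4 against 22.9 ± 5.98 CPM and rose by 4.12 ± 0.22 (adjusted p = 1.9e-08), and FOSB rose by 4.07 ± 0.38. The list as a whole went both ways, with 12 of 23 members up and 8 down, 9 when adjusted over the list alone (adjusted p = 0.35). The growth regulator MYC fell by 2.08 ± 0.11 and the phosphatase gene DUSP6 by 1.84 ± 0.14, while the phosphatase gene DUSP2 rose by 3.83. Other large rises were in the gap junction gene GJD2 (3.47 ± 0.40), the protease inhibitor gene A2M (2.91 ± 0.29, from 783 ± 288 to 5837 ± 2144 CPM) and the GABA receptor subunit gene GABRA3 (2.84 ± 0.41). Other large falls were in the microfibril gene MFAP4, by 4.09 ± 0.52, the collagenase gene MMP13, by 3.97 ± 0.49, and the epithelial keratins KRT17 and KRT5, by 3.77 ± 0.50 and 3.55 ± 0.27.

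**Figure D3:**
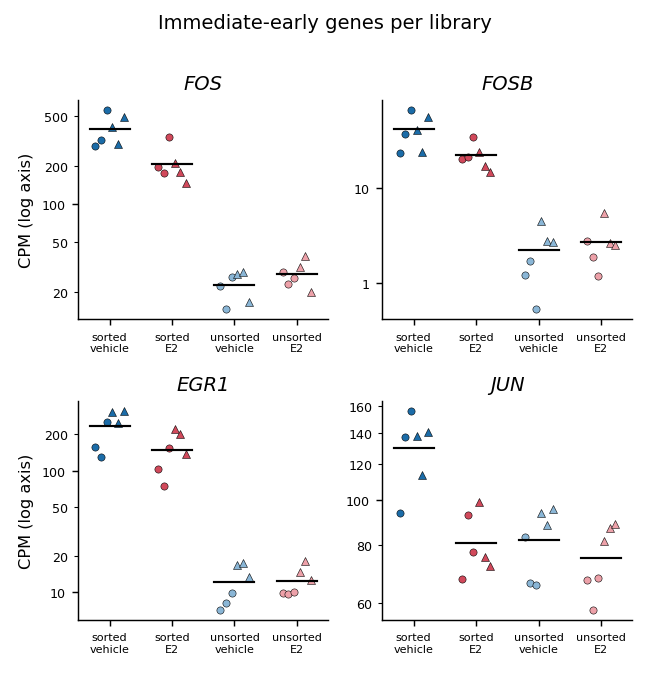
CPM (log axis) of FOS, FOSB, EGR1 and JUN in each library of the 4 groups, with circles for replicates 1 to 3, triangles for replicates 4 to 6 and bars for group means. FOS averaged 395 CPM in sorted and 22.9 CPM in unsorted vehicle libraries.

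Of 19 ribosomal protein genes 11 fell and 1 rose (median -0.42; camera adjusted p = 0.037; adjusted p = 0.375 with an estimated correlation). Of 10 mitochondrially encoded genes 5 rose, among them CYTB by 1.26 (median 1.11; camera adjusted p = 0.12, 0.041 with the block and 0.366 with block and estimated correlation). Mitochondrial genes took 1.22 ± 0.523% of counts in sorted and 0.548 ± 0.286% in unsorted vehicle libraries. Of 25 interferon-stimulated genes 8 rose, 7 when adjusted over the list alone, among them the RNA sensor gene DDX58 by 1.37 (camera adjusted p = 0.065, 0.021 with the block and 0.461 with block and estimated correlation). Estrogen targets known from other tissues split, with 5 of 25 up and 11 down (adjusted p = 0.12), and TGFA fell by 2.62 ± 0.22. Heat shock genes (0 up and 2 down of 8, adjusted p = 0.35), endoplasmic reticulum stress genes (5 up of 17, 0.069), p53 targets (1 up and 4 down of 9, 0.23) and cholesterol synthesis (5 up and 3 down of 16, 0.35) did not pass as lists.

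In all, 7267 of 14468 genes differed by the edgeR test, 3529 higher and 3738 lower in sorted libraries. Of these, 780 were at least 2-fold higher and 1984 at least 2-fold lower. Replicates 1 to 3 alone gave 5655 calls and replicates 4 to 6 alone 8594, and 6841 of the 6858 called genes tested in both sets had 1 sign in both. The authors' deposited table called 7345 genes, of which 6479 are among the 7267. The labels do not say whether unsorted cells passed through the sorter, so sorting and handling are not told apart. Each gene named as risen or fallen in the vehicle and E2 comparisons moved in that direction in 6 of 6 same-numbered comparisons.

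E2 in sorted cells raised more genes than it lowered. RAPGEFL1 (ENSOARG00000013357), a guanine nucleotide exchange factor-like gene, stood at 76.9 ± 20.5 CPM (SD, n = 6) with E2 and 12.8 ± 4.98 CPM with vehicle and rose by 2.63 ± 0.24 (log2 ± SE; adjusted p = 0.00017, edgeR). AQP1, a water channel gene, stood at 38.9 ± 19.3 against 7.67 ± 3.64 CPM and rose by 2.38 ± 0.38 (adjusted p = 0.0051). GNRHR stood at 21.6 ± 12.2 against 5.61 ± 2.24 CPM and rose by 1.98 ± 0.38 (adjusted p = 0.018; 1.63 and 2.18 in replicates 1 to 3 and 4 to 6). Its call was lost without sorted vehicle replicate 2, 3 or 6 (adjusted p up to 0.054).

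Of 23 tested estrogen targets from other tissues, 4 rose and none fell by the edgeR test, or 8 and 1 with the replicate block (median 0.15; camera adjusted p = 0.00014; adjusted p = 0.0858 with an estimated correlation). The retinoic acid receptor gene RARA rose by 1.63 ± 0.17 (adjusted p = 0.00035), the small GTPase gene RASD1 by 1.30 ± 0.22 and the nuclear receptor corepressor gene NRIP1 by 1.07 ± 0.18. GREB1 stood at 88.6 ± 34.1 against 20.1 ± 15.6 CPM and rose by 2.18 ± 0.47 (adjusted p = 0.041), a call lost in 10 of the 12 fits that each left out 1 library (adjusted p up to 0.11), all but those without sorted vehicle replicate 1 and sorted E2 replicate 2. Of 12 steroid receptor and coregulator genes 3 rose and 1 fell, or 4 and 2 adjusted over the list alone and 6 and 4 with the block, and the corepressor gene NCOR1 rose by 0.35 ± 0.05. ESR1 itself stood at 36.8 ± 3.43 CPM with E2 and 50.3 ± 7.73 CPM with vehicle. Its difference of -0.42 missed the unblocked threshold (adjusted p = 0.069, or 0.035 without sorted vehicle replicate 1), and with the replicate block it fell by 0.45 ± 0.06 (adjusted p = 3.7e-05). The exact permutation test of log2 CPM gave adjusted p = 0.0173 for ESR1, GNRHR and GREB1 each. The exact sign-flip test over same-numbered libraries gave adjusted p = 0.075 for each of them.

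**Figure D4:**
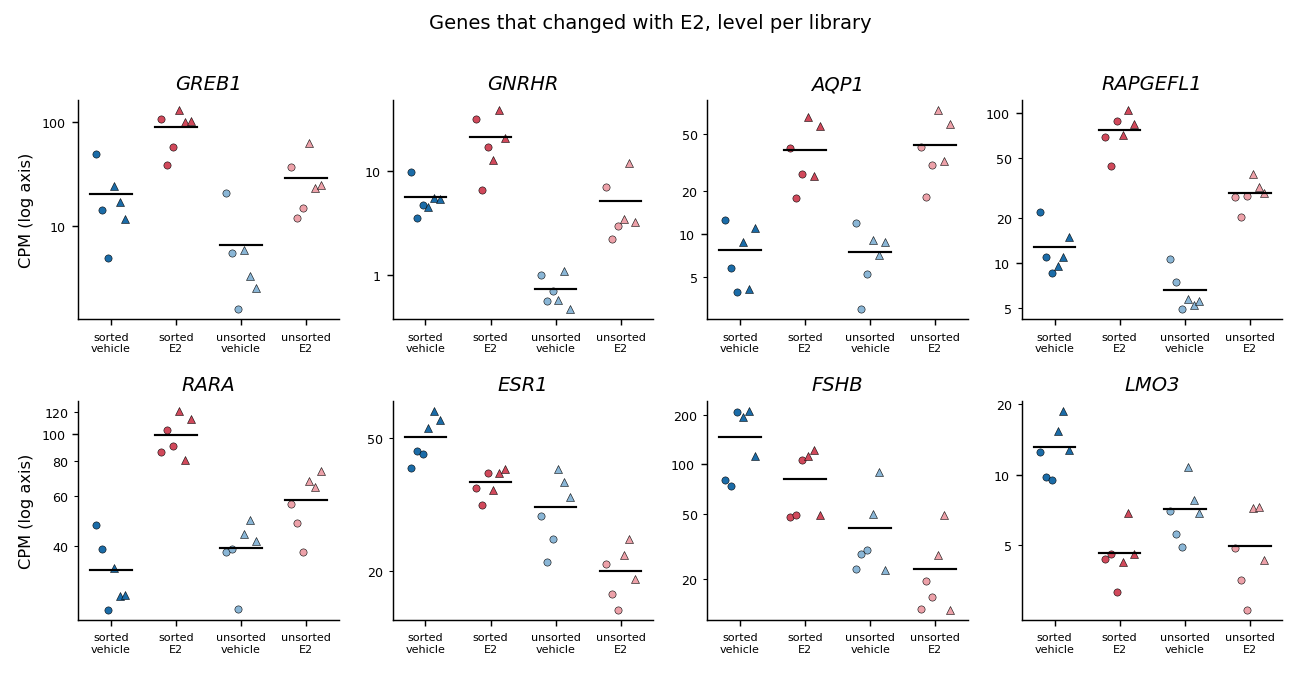
CPM (log axis) of 8 genes in each library of the 4 groups, with circles for replicates 1 to 3, triangles for replicates 4 to 6 and bars for group means. RAPGEFL1 averaged 76.9 CPM with E2 and 12.8 CPM with vehicle in sorted cells.

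Among the gonadotropin genes, FSHB was lower with E2 in 6 of 6 same-numbered comparisons, at 81.0 ± 36.0 CPM against 147 ± 65.7 CPM. Its difference of -0.83 ± 0.35 did not pass the unblocked test (adjusted p = 0.60), and with the replicate block it fell by 0.84 ± 0.06 (adjusted p = 7.1e-08; -0.77 and -0.90 in the 2 sets). LHB stood at 1007 ± 469 CPM with E2 and 1029 ± 527 CPM with vehicle, and CGA at 2604 ± 579 and 2787 ± 758 CPM. LHB, CGA, NR5A1, PRL, GH, POMC and S100B passed with neither fit. TSHB fell by 0.30 ± 0.05 with the block (adjusted p = 0.00012), against -0.27 ± 0.51 without (adjusted p = 1.00).

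Genes lowered by E2 in sorted cells included LMO3, a LIM domain transcription regulator, which fell by 1.46 ± 0.20 (adjusted p = 0.0018), from 13.1 ± 3.50 to 4.64 ± 1.22 CPM. RGS2, a regulator of G protein signalling, fell by 0.88 ± 0.10 (adjusted p = 0.00043), and SPRY1, an inhibitor of growth factor signalling, by 0.91 ± 0.15. POU1F1 fell by 0.75 ± 0.10 (adjusted p = 0.0010), and the neuronal RNA-binding protein gene ELAVL4 by 0.76 ± 0.11. The thyrotropin-releasing hormone receptor gene TRHR fell by 1.00 ± 0.20 (adjusted p = 0.023), a call lost without sorted vehicle replicate 2, 3 or 5 or sorted E2 replicate 4 or 6 (adjusted p up to 0.067). The lactotrope list, which holds TRHR, had a median of -0.34, with 1 of 6 down, or 3 with the block (camera adjusted p = 0.026; adjusted p = 0.279 with an estimated correlation). Other genes that rose were TMEM37, a calcium channel subunit-like gene, by 2.04 ± 0.21, the glycosyltransferase gene MGAT3 by 2.16 ± 0.28 and the transcription corepressor gene CBFA2T3 by 1.99 ± 0.31.

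Immediate-early genes were mostly lower with E2 in sorted cells. Of 23 members 4 had positive and 19 negative or zero changes, 1 fell and 0 rose by the edgeR test, 4 fell when adjusted over the list alone, 8 fell and 2 rose with the block, and the median was -0.27 (camera adjusted p = 6.8e-06; adjusted p = 0.0858 with an estimated correlation and 0.538 with block and estimated correlation). The member past the unblocked test was JUN, a subunit of the AP-1 transcription factor, which fell by 0.66 ± 0.13 (adjusted p = 0.026), a call lost in 8 of the 12 left-out fits (adjusted p up to 0.075) and kept without sorted vehicle replicate 1 or 5 or sorted E2 replicate 2 or 4. FOS fell with the block by 0.90 ± 0.17 (adjusted p = 0.025) and differed by -0.88 without it (adjusted p = 0.077, or 0.010 without sorted E2 replicate 3). Of 30 GnRH signalling genes 1 rose (GNRHR) and 2 fell (RGS2 and JUN), or 2 and 6 adjusted over the list alone and 2 and 9 with the block. The list's median was -0.06 (camera adjusted p = 0.034; adjusted p = 0.0858 with an estimated correlation and 0.087 with the block). It shares JUN, FOS, EGR1, ATF3 and DUSP1 with the immediate-early list, so the 2 list results are not independent. Secretory granule genes passed only with the block, with a median of -0.08 (camera adjusted p = 0.056 without, 0.022 with; adjusted p = 0.935 with block and estimated correlation). The other 20 lists tested did not pass in sorted cells with either fit.

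In all, 196 of 14334 genes differed by the edgeR test, 159 higher and 37 lower with E2, with 78 raised and 2 lowered at least 2-fold. With the replicate block 1896 differed, 1008 higher and 888 lower, the 196 among them. Replicates 1 to 3 alone gave 22 calls and replicates 4 to 6 alone 146 (563 and 1277 with the block), and 192 of the 192 called genes tested in both sets had 1 sign in both. The authors' deposited table called 211 genes, of which 163 are among the 196. The count fell to 125 without sorted vehicle replicate 3 and to 130 without sorted vehicle replicate 2.

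In unsorted cells E2 raised several of these genes too. GNRHR stood at 5.16 ± 3.73 CPM with E2 and 0.728 ± 0.255 CPM with vehicle and rose by 2.86 ± 0.44 (adjusted p = 0.016, edgeR; 2.37 and 3.07 in replicates 1 to 3 and 4 to 6). Its call was lost without unsorted vehicle replicate 4 or 6 (adjusted p up to 0.066). AQP1 stood at 42.3 ± 20.3 against 7.54 ± 3.15 CPM and rose by 2.48 ± 0.34 (adjusted p = 0.0064), and RAPGEFL1 stood at 29.3 ± 6.14 against 6.58 ± 2.15 CPM and rose by 2.20 ± 0.20 (adjusted p = 0.00043).

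The proteoglycan gene SDC3 rose by 1.55 ± 0.20 (adjusted p = 0.0064), the adenylyl cyclase gene ADCY5 by 1.49 ± 0.21 and the cell adhesion gene NECTIN1 by 1.37 ± 0.19. CHRM3, a muscarinic acetylcholine receptor gene, fell by 1.37 ± 0.22 (adjusted p = 0.019), from 11.3 ± 3.59 to 4.35 ± 1.02 CPM, a call lost without unsorted vehicle replicate 4, 5 or 6 or unsorted E2 replicate 1, 5 or 6 (adjusted p up to 0.068). The other 4 lowered genes, ZBTB7C, EPHA3, JAKMIP1 and ERICH3, had changes of -1.14, -0.93, -0.92 and -0.51 and were lost in 7, 9, 12 and 9 of the 12 fits that each left out 1 library (adjusted p up to 0.077, 0.098, 0.16 and 0.078). ZBTB7C was kept without unsorted vehicle replicate 1, 2 or 3 or unsorted E2 replicate 2 or 6, EPHA3 without unsorted vehicle replicate 1 or 5 or unsorted E2 replicate 1, and ERICH3 without unsorted vehicle replicate 1 or unsorted E2 replicate 2 or 3.

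FSHB was lower with E2 in 6 of 6 same-numbered comparisons here as well, at 22.9 ± 13.9 CPM against 40.5 ± 26.0 CPM. The difference was -0.81 ± 0.39 without the block (adjusted p = 1.00), and FSHB fell by 0.82 ± 0.06 with it (adjusted p = 1.5e-08; -0.78 and -0.83 in the 2 sets). ESR1 stood at 19.9 ± 3.51 against 31 ± 7.31 CPM, -0.64 without the block (adjusted p = 0.17), and fell by 0.67 ± 0.07 with it (adjusted p = 1.8e-06). GREB1 stood at 28.7 ± 18.4 against 6.56 ± 7.14 CPM, 2.24 ± 0.57 without the block (adjusted p = 0.21), and rose by 2.66 ± 0.43 with it (adjusted p = 0.032). Unsorted vehicle replicate 1 held 20.8 CPM of GREB1, and without that library GREB1 was called with 2.95 (adjusted p = 0.013). The exact permutation test of log2 CPM in unsorted cells gave adjusted p = 0.0346 for ESR1 and GREB1 and 0.0260 for GNRHR. The exact sign-flip test gave adjusted p = 0.075 for each of these genes. LHB, CGA, NR5A1, PRL, GH, POMC, TSHB and S100B passed with neither fit. Further genes past the blocked test alone were POU1F1, which fell by 0.52 ± 0.05 (adjusted p = 4.7e-07; 0.17 unblocked), TRHR, which fell by 0.52 ± 0.08 (0.00030; 1.00 unblocked), and RARA, which rose by 0.58 ± 0.06 (2.9e-06; 0.46 unblocked).

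Of 27 estrogen targets from other tissues 23 had positive changes, 0 passed the edgeR test, 1 rose when adjusted over the list alone and 4 rose with the block. The list's median was 0.06 (camera adjusted p = 0.030; adjusted p = 0.115 with an estimated correlation). Lactotrope markers had a median of -0.08 with 0 of 6 past the edgeR test, 1 down when adjusted over the list alone and 3 down and 1 up with the block (camera adjusted p = 0.031; adjusted p = 0.172 with an estimated correlation and 0.28 with the block). Interferon-stimulated genes passed only with the block (median -0.11; camera adjusted p = 0.23 without, 0.016 with; adjusted p = 0.938 with block and estimated correlation). Immediate-early genes, with 15 of 23 positive, did not pass (adjusted p = 0.20), nor did the other 21 lists tested with either fit.

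In all, 37 of 15083 genes differed by the edgeR test, 32 higher and 5 lower with E2, and 790 with the replicate block (432 higher and 358 lower), the 37 among them. Replicates 1 to 3 alone gave 0 calls by edgeR (322 genes at unadjusted p under 0.05; 67 calls with the block) and replicates 4 to 6 alone 20 (730 with the block), and 32 of the 32 called genes tested in both sets had 1 sign in both. The authors' deposited table called 77 genes, of which 35 are among the 37. The count rests on single libraries: it was 13, 20 and 14 without unsorted vehicle replicates 4, 5 and 6, and 21, 18, 11 and 17 without unsorted E2 replicates 1, 4, 5 and 6.

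The series title asks whether enrichment sharpens the view of the E2 response, so the 2 responses were compared gene by gene. Among 14144 genes tested in both, 156 rose in sorted and 30 in unsorted cells, and 20 rose in both, against 0.331 if calls were independent (Fisher's exact test, 2-sided, p = 5.5e-33). The shared rises included RAPGEFL1, AQP1, GNRHR, SDC3 and NECTIN1. ERICH3 was the 1 shared fall, against 0.0131 if independent (Fisher's exact test, p = 0.013), and its call in unsorted cells held only without unsorted vehicle replicate 1 or unsorted E2 replicate 2 or 3 among the left-out fits (adjusted p up to 0.078). With the replicate block 339 rises and 194 falls were shared. Of the 156 rises in sorted cells 154 were positive in unsorted cells, where their median was 0.46 against 0.99 in sorted cells, and the 30 rises in unsorted cells had medians of 1.43 and 1.45. Such medians favour the comparison in which the genes were called, and genes are not independent replicates.

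**Figure D5:**
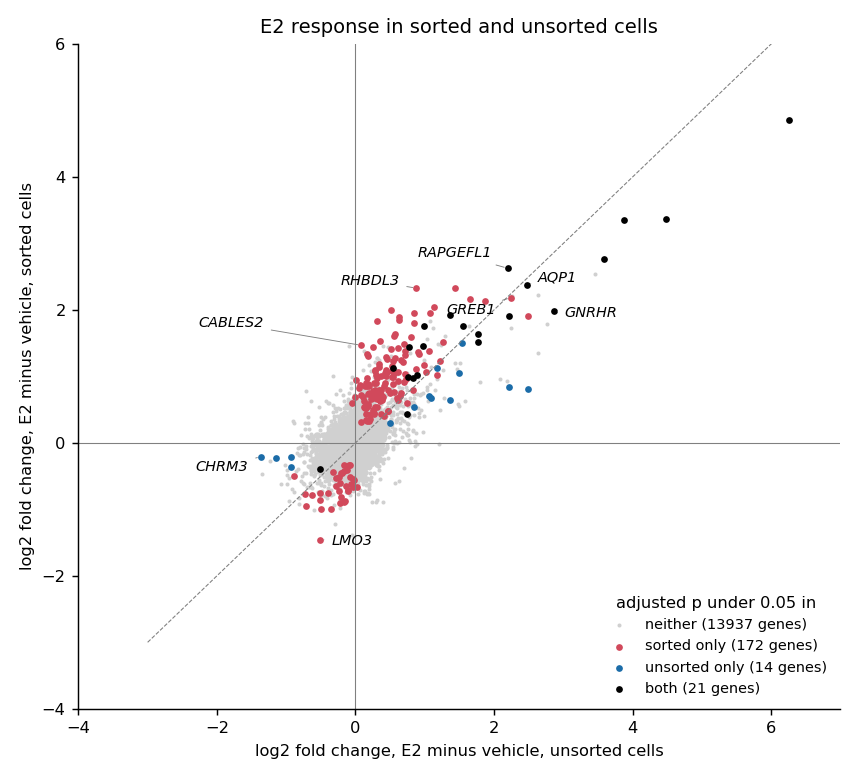
Log2 fold change with E2 in unsorted (x axis) against sorted cells (y axis) for 14144 genes, coloured by the comparison in which they were called, with a dashed line of equality. In all 172 genes were called in sorted cells alone, 14 in unsorted cells alone and 21 in both.

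The difference of the E2 effects, tested directly, passed for 4 genes, all more raised in sorted cells. CABLES2, a cyclin-dependent kinase-interacting gene, differed by 1.38 ± 0.24 (adjusted p = 0.031, edgeR; 1.61 and 1.12 in replicates 1 to 3 and 4 to 6). With E2 and vehicle it stood at 9.52 ± 1.84 and 3.47 ± 0.620 CPM in sorted cells and 5.82 ± 0.899 and 5.49 ± 1.06 CPM in unsorted cells. KREMEN1, a Wnt pathway receptor gene, differed by 1.13 ± 0.21 (adjusted p = 0.046), PLEKHM1, a lysosomal trafficking gene, by 0.80 ± 0.14 (0.031) and TTLL4, a polyglutamylase gene, by 0.63 ± 0.11 (0.031). Their calls were lost in 20, 22, 20 and 21 of the 24 fits that each left out 1 library (adjusted p up to 0.13, 0.15, 0.13 and 0.13). All 4 were kept without sorted E2 replicate 2, all but CABLES2 without sorted vehicle replicate 1, and all but KREMEN1 without unsorted E2 replicate 4. CABLES2 was also kept without unsorted vehicle replicate 1 or sorted E2 replicate 6, and PLEKHM1 without unsorted vehicle replicate 3.

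With the replicate block more genes differed, among them 3 estrogen targets more raised in sorted cells: RARA by 1.09 ± 0.21 (adjusted p = 0.018; 0.25 unblocked), RASD1 by 0.83 ± 0.15 (0.0091; 1.00 unblocked) and NRIP1 by 0.77 ± 0.10 (0.00050; 0.78 unblocked). RGS2 and FOS responded more negatively in sorted cells, with differences of -0.74 ± 0.11 (0.0021; 0.25 unblocked) and -1.23 ± 0.26 (0.043; 0.40 unblocked). The cell cycle gene TOP2A differed by 0.83 ± 0.14 (0.0046; 0.71 unblocked). TSHB differed by -0.40 ± 0.62 and passed only with the block within each cell type (adjusted p = 0.00029; 1.00 unblocked). For the 12 fixed genes the differences ranged from -0.88 (GNRHR, adjusted p = 1.00) to 0.22 (ESR1, 1.00), and 0 of them passed the unblocked edgeR test.

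As a group, immediate-early genes had a more negative E2 minus vehicle change in sorted cells. FOS, FOSB and EGR1 of this list were far higher in sorted than in unsorted vehicle libraries. Whether handling during the sort bears on the difference was not tested. The median difference was -0.40, with 2 of 23 positive (camera adjusted p = 1.2e-11; adjusted p = 0.00759 with an estimated correlation). Thyrotrope markers had a median of -0.45, 0 of 4 positive (adjusted p = 0.014; adjusted p = 0.0854 with an estimated correlation and 0.0319 with block and estimated correlation), and estrogen targets 0.14, 17 of 27 positive (adjusted p = 0.024; adjusted p = 0.125 with an estimated correlation). GnRH signalling genes had a median of -0.0055 and a mean of -0.13 (adjusted p = 0.013; adjusted p = 0.119 with an estimated correlation). They include EGR1, JUN, FOS, ATF3 and DUSP1 of the immediate-early list, so the results of these 2 lists are not independent. In these 4 lists 0 single members passed the unblocked edgeR test over all genes, and adjusted over the list alone 1 immediate-early and 2 GnRH signalling genes were lower and 2 estrogen targets higher. Lactotrope markers passed only with the block (median -0.22; adjusted p = 0.28 without, 0.012 with; adjusted p = 0.236 with block and estimated correlation).

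Of 15134 genes 4 differed without the block, 70 with it (50 higher and 20 lower) and 357 with the block within each cell type (251 and 106). Replicates 1 to 3 and 4 to 6 alone gave 0 calls each by edgeR (245 and 402 genes at unadjusted p under 0.05), and 22 and 162 with the block within each cell type. The 4 calls rest on single libraries: fits without sorted vehicle replicate 1, sorted E2 replicate 2 or unsorted E2 replicate 4 gave 4, 4 and 3 calls, and fits without any other library gave 0 or 1 (191 to 277 at unadjusted p under 0.05).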

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

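The tests of library depth, of the loss of non-endocrine cells, of cells of other hormone types, of a few libraries and of handling during the sort were chosen after the results were seen, as were the thinned fits and those without number 1.

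Levels of the named genes and library measures, such as total counts and the mitochondrial share, formed 124 groups of 6 libraries. Of these groups 4, all formed by a gene, held 1 library far from the rest, and chance gives about 1 in 20. FOS in sorted E2 replicate 3 was at 342 CPM, against 147 to 212 in the others. GNRHR in sorted vehicle replicate 1 was at 9.96 CPM (3.55 to 5.54), FOSB in unsorted E2 replicate 4 at 5.47 CPM (1.16 to 2.72) and GREB1 in unsorted vehicle replicate 1 at 20.8 CPM (1.58 to 5.85).

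The E2 effect differed between sorted and unsorted cells, by the interaction test, in 4 genes: CABLES2 (1.38), KREMEN1 (1.13), PLEKHM1 (0.80) and TTLL4 (0.63). It differed in 4 gene lists by camera: estrogen targets from other tissues (median 0.14), GnRH signalling (-0.0055), immediate-early genes (-0.40) and thyrotrope markers (-0.45). The GnRH signalling and immediate-early lists share members. With an estimated correlation the immediate-early list alone held without the block (adjusted p = 0.00759), and thyrotrope markers passed as well with it (0.0319).

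The first pattern weighed is the larger number of E2 calls in sorted cells, 196 against 37 without and 1896 against 790 with the replicate block. The values argue against library depth as the cause, since it points the other way: in replicates 4 to 6 unsorted libraries held 32.1 to 37 M counts and sorted ones 19.2 to 22.5 M. Replicates 1 to 3 held 5.03 to 5.98 M in unsorted and 4.19 to 6.19 M in sorted libraries and gave 67 and 563 blocked calls. Thinning to the lowest total, which takes more from the unsorted libraries, left 1337 sorted and 367 unsorted blocked calls, a ratio of 3.64. A smaller spread between sorted libraries cannot be told apart from other causes, because the ratio of common dispersions was 0.97 and ranged from 0.611 to 1.36 with each number left out. A candidate explanation that fits its test is dilution by cells that do not respond, which would weaken most the E2 effect on genes those cells express too. Among genes raised by E2, enrichment by sorting and the difference of the E2 effect correlated across genes at Spearman's rho = -0.162, below all 10000 matched random gene sets (median 0.0637), although the correlation is small. The random sets were drawn from all genes, most of them not raised by E2. They show that raised genes differ from others of like expression, which does not establish dilution.

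The second pattern is the higher level of PRL, GH, TSHB and POMC in sorted vehicle libraries. The values argue against normalization as the cause, since with library totals alone the lowest of the 4 mean log2 differences was 0.790. Loss of non-endocrine cells met the values set for it, but these do not decide the question. The 4 differences spread over 0.377, within 2 of their largest SD over numbers (0.422), and the fibroblast list had a median of -2.38. A bound in SDs rather than SEs is wide. Such a loss would also raise these genes only if cells that hold their transcripts were in the sorting gate. Cells of other hormone types in the sorting gate cannot be told apart from gonadotropes that hold these transcripts, with PRL at 121048 CPM beside CGA at 2787 CPM, because no single cells were measured. The design gives no group that isolates a biological explanation, and none beyond these changes in cell makeup was examined.

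The third pattern is the higher level of FOS, FOSB and EGR1 in sorted vehicle libraries. The values argue against a few libraries as the cause, since all 3 genes were higher in the sorted library in 6 of 6 numbers. Handling during the sort may have induced them, and 12 of 23 immediate-early genes rose while 8 fell. Enrichment of gonadotropes, the biological difference the design gives, would raise no transcript more than one found only in gonadotropes. GNRHR and NR5A1, taken as such transcripts, had mean log2 differences of 2.75 and 2.61 (SD over numbers 0.389 and 0.581). CGA (2.82, SD 0.443) is shared by the glycoprotein hormones and is not taken as one. EGR1, FOS and FOSB rose by 4.07 to 4.23 by edgeR, a measure that put GNRHR above 2.75 but below these 3. This argues against enrichment alone as the cause for these 3 genes, as far as GNRHR and NR5A1 set the limit. That limit is uncertain, since GJD2, which is not in the immediate-early list, also rose by more than GNRHR. Whether handling induced them was not tested, because the labels do not say whether unsorted cells were handled in the same way.

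Other splits of the same libraries were fitted in the same way. In the sorted against unsorted vehicle comparison 1 of 100 splits, the real one, gave as many calls (7267, highest other 1429). The same share held for E2 in sorted cells (196, highest other 0 by edgeR) and in unsorted cells (37, highest other 0). Most of the other splits placed both libraries of some numbers in 1 group, unlike the real one. Differences between numbers therefore entered their contrasts, and those between treatments or preparations entered their spread. Because they are unlike the real split in both ways, they do not exclude chance for these 3. For the difference of the E2 effects 5 of 100 labellings gave at least the real 4 calls (highest other 6748), so chance is not excluded without the block. The labellings with 6748 and 1626 calls placed 4 and 3 more deep libraries under E2 in sorted than in unsorted cells. Other labellings with a difference of 3 gave 0 calls, so depth alone does not account for the counts. Splitting each comparison by depth set gave 1828, 5698 and 8264 calls. With the replicate block, the real one alone of 32 splits that part every pair gave as many calls. The counts were 9198 (highest other 0), 1896 (16), 790 (215) and, for the difference of the E2 effects, 357 (1). A share of 1 in 32 is the smallest these splits can give, so chance is unlikely but not excluded. In these the other splits exchange the treatment within some numbers.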

How the results depend on the processing

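The depth set term, the fits within sets, thinning and the fits without number 1 were chosen after the results were seen.

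The sorted against unsorted comparison was the most stable: its count lay between 5203 and 9198 under the alternatives other than a test against a 1.5-fold change (2613) and replicates 4 to 6 with the replicate block (10423), and between 6170 and 7368 with each library left out. Of 71 named genes in it 70 were called, and 68 of these in each fit that left out a library and still tested them, which was 6 of 12 fits for IL1B and 9 of 12 for CSF1R. The E2 counts depend on the test, the depth and the pairing. The replicate block raised the E2 counts by over 1.5 times and added calls of 1, 12 and 13 named genes in the first 3 comparisons, not all of which are given in the text. Where no reason is given, the cause was not tested.

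For E2 in sorted cells (196 calls) the count was 401 by DESeq2, 1896 with the replicate block (1726 without number 1), 103 at adjusted p under 0.01, 37 against a 1.5-fold change, 505 with a depth set term, 22 in replicates 1 to 3, 157 with thinning and 1337 with thinning and the block. With each library left out it was 125 to 208, the lowest without sorted vehicle replicate 3, and 130 without sorted vehicle replicate 2.

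For E2 in unsorted cells (37 calls) the count was 124 by DESeq2, 73 by limma-voom, 790 with the replicate block (764 without number 1), 104 by the edgeR exact test, 73 with all 24 libraries in 1 fit, 12 at adjusted p under 0.01, 11 against a 1.5-fold change and 143 with a depth set term. It was 0 in replicates 1 to 3 by edgeR (322 at unadjusted p under 0.05), 20 in replicates 4 to 6, 12 with thinning and 367 with thinning and the block. With each library left out it was 11 to 48, the lowest without unsorted E2 replicate 5 and the highest without unsorted vehicle replicate 1. It was 13, 20 and 14 without unsorted vehicle replicates 4, 5 and 6, and 21, 18 and 17 without unsorted E2 replicates 1, 4 and 6.

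For the difference of the E2 effects (4 calls) the count was 22 by DESeq2, 70 with the replicate block, 357 with the block within each cell type (332 without number 1), 15 with a depth set term and 4 by limma-voom. By edgeR it was 0 with no filter (441 at unadjusted p under 0.05), 0 in replicates 1 to 3 (245), 0 in replicates 4 to 6 (402), 0 without number 1 (220) and 0 with thinning (238). With each library left out it was 0 to 4, at 4, 4 and 3 without sorted vehicle replicate 1, sorted E2 replicate 2 and unsorted E2 replicate 4 and at 0 or 1 without any other (191 to 277 at unadjusted p under 0.05). The shared rises of the E2 comparisons (20) were 339 with the block, 73 by DESeq2 and 35 at adjusted p under 0.10, and the shared falls (1) were 194 with the block and 8 by DESeq2.

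Camera called 10, 4, 2 and 4 lists in the 4 comparisons, 15, 4, 2 and 5 with the replicate block, and 1, 0, 0 and 1 with an estimated correlation and no block. With no filter it called 17 in the first and 0 in unsorted cells with E2.

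Changes of sign were found in hormone and marker genes called in none of these fits. The LHB log2 fold change, E2 minus vehicle, sorted cells, was -0.0041 with DESeq2's size factors, -0.0017 with no filter, -0.0074 with the stricter filter, -0.0042 by DESeq2, -0.014 with the depth set term and -0.071 in replicates 1 to 3. NR5A1 was 0.011 by limma-voom and 0.013 in replicates 4 to 6, CGA was 0.019 in replicates 1 to 3 and POMC 0.074 in replicates 4 to 6. In replicates 1 to 3, the NR5A1 log2 fold change, E2 minus vehicle, unsorted cells, was -0.056, and the GH log2 fold change, E2 minus vehicle, unsorted cells, was -0.0010. With each library left out, sorted cells gave ranges of -0.20 to 0.072 for PRL, -0.19 to 0.22 for LHB, -0.16 to 0.024 for CGA, -0.20 to 0.094 for NR5A1, -0.52 to 0.38 for GH, -0.24 to 0.17 for POMC and -0.61 to 0.055 for TSHB. Unsorted cells gave -0.47 to 0.60 for LHB, -0.084 to 0.29 for CGA, -0.23 to 0.28 for NR5A1, -0.16 to 0.01 for S100B, -0.51 to 0.60 for GH, -0.0027 to 0.25 for POMC and -0.024 to 0.28 for TSHB.

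Of the named genes 31 were called with E2 in sorted cells, 21 of them in each left-out fit, and 14 in unsorted cells, 5 of them in each. Of the 4 genes called in the interaction 0 were called in every left-out fit.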

Other observations

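The fits without number 1 were added after the results were seen, whereas the tests of the 3 hypotheses below were set down before their values were seen.

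Further genes passed with the replicate block alone after E2. In sorted cells genes of the activin and BMP pathway went both ways: FST, the follistatin gene, fell by 0.54 ± 0.10 (log2 ± SE, n = 6 pairs; edgeR adjusted p = 0.00065; 0.25 unblocked), and SMAD1, a BMP signal transducer, fell by 0.36 ± 0.06 (0.00013; 0.19 unblocked). ACVR1B, an activin receptor gene, rose by 0.41 ± 0.07 (0.00020; 0.063 unblocked, or 0.032 without sorted E2 replicate 1). Of 27 members 4 rose and 6 fell with the block, and the list did not pass (adjusted p = 0.49 with the block). RAB3A, a GTPase of secretory vesicles, fell by 0.44 ± 0.06 (4.1e-05; 0.19 unblocked) and IRF1, an interferon response factor, by 0.61 ± 0.07 (2.7e-06; 0.099 unblocked). In unsorted cells DIO2, a deiodinase that activates thyroid hormone, rose by 1.01 ± 0.10 (0.00014; 0.16 unblocked), and PRKCB, a protein kinase C gene, fell by 0.65 ± 0.09 (4.2e-05; 0.17 unblocked). GADD45A, a p53 target, rose by 0.50 ± 0.05 there with the block (4.3e-06; 0.053 unblocked, or 0.047 without unsorted E2 replicate 3) and by 0.80 ± 0.11 in sorted cells without it (0.0020).

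Genes that responded to E2 tended to be higher in sorted than in unsorted libraries. Over both preparations 952 genes rose and 1026 fell with E2 in a blocked fit of all 24 libraries. With enrichment averaged over vehicle and E2 libraries, the raised genes had a median of 0.323 (log2, sorted minus unsorted), against a median of 0.0316 in 10000 random sets matched for expression, and lay above all of these. The lowered genes had a median of 0.491 and lay above all of their matched sets too. Of the raised genes 69.5% and of the lowered genes 80.3% were higher in sorted libraries, against 51.3% of all genes. These values fit what was set down for the hypothesis that many E2-responsive transcripts come from the cells that the sort enriches. They do not establish it, since both medians lie well below the mean log2 difference of CGA in vehicle libraries (2.82). Sorted cells also gave more E2 calls, which may favour genes higher there. Of the raised genes, 116 were at least 2-fold higher and 36 at least 2-fold lower in sorted libraries, and their median differences of the E2 effect were 0.0991 and 0.283.

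The vehicle libraries of number 1 held higher levels of genes that E2 raised at least 2-fold in the other 5 numbers. The median log2 deviation from the other vehicle libraries was 0.530 over 86 genes in unsorted cells (64 above the mean of the others) and 0.470 over 160 genes in sorted cells (122 above). The highest of the other numbers, each left out in the same way, was 0.221. The E2 change of number 1 was smaller, with medians of 0.904 in sorted and 0.992 in unsorted cells, against 1.35 and 1.56 in the other numbers. A raised vehicle level lowers this change by arithmetic, and number 2 had small E2 changes too (1.10 and 0.763) with vehicle deviations of -0.113 and 0.126, so a small change does not speak for the hypothesis. An estrogen response already present in the vehicle cultures of number 1 may be the reason for the higher levels, as a hypothesis. The vehicle deviations fit what was set down for it. Number 1 also stood apart in GREB1 and GNRHR in these same data, and same-numbered libraries deviate together. The 2 preparations therefore do not test the hypothesis independently. Without number 1 the E2 comparisons gave 170 calls in sorted and 31 in unsorted cells (1726 and 764 with the block).

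The comparison of sorted with unsorted cells was also made among E2-treated libraries, where 7533 of 14545 genes differed by the edgeR test, 3749 higher and 3784 lower in sorted cells. Replicates 1 to 3 gave 6430 calls and replicates 4 to 6 gave 8145.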
